A study of Mus musculus with 6 samples.

How the data were processed

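RNA from HL-1 cells, a cardiomyocyte line derived from a mouse atrial tumour, was measured on 6 one-colour Affymetrix mouse arrays. Per the labels' protocols, confluent cells were kept for 8 hours at 1% or 21% oxygen, total RNA was extracted with a column kit, and biotinylated cRNA was prepared by the array maker's standard protocol. The labels assign 3 samples to each condition. They do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

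The values used were the authors' deposited intensity of each probe set on a linear scale, 1 value per probe set and array. Per the submitters' processing notes the software was MAS5; its version and settings are not given in the sources used here. The table held 45037 probe sets. The mean signal after trimming 2% of the probe sets at each end was 99.5 on all 6 arrays, so the deposited arrays share one scale, and no further scaling was applied. MAS5 signals come from 1 array at a time and vary widely near background, and the number of arrays limits the precision. Detection calls were not used here. The table used here held 0 control probe sets of the array maker, so a planned ratio of 3' to 5' signal, a sign of RNA quality, could not be computed. None of the 15 pairs of arrays held identical values.

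For testing, 10 values of 0 were set to the smallest signal above 0, which was 0.1, and all values were log2 transformed. Probe sets were kept where their mean log2 signal over the 6 arrays lay above the median over all probe sets, equal to a geometric mean signal of 14.1. This kept 22518 probe sets. Hypoxia was compared with normoxia with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean signal, two-sided), without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets kept. A change was called at an adjusted p under 0.05. Fold changes are hypoxia over normoxia on the log2 scale, with the moderated standard error (SE) of limma. Group signals are given as mean ± SD of 3 arrays on the linear scale. An exact permutation test of 3 against 3 cannot give a p below 0.1, so single genes rest on the spread shared across probe sets.

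Probe sets were named from a platform annotation dated 2016. In the copy used here, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Some of its symbols differ from those in the fixed lists, such as Ccn1 for Cyr61, so the names may be newer than that year. Gene IDs were looked up in the RefSeq annotation of GRCm38.p6, which changed 0 symbols; 204 probe sets with 1 symbol had a gene ID that did not match. No genome build belongs to the array values, so no coordinates are given. Each gene was represented by the kept 1-symbol probe set with the highest mean signal, which gave 11332 genes. Probe sets with several symbols were tested but counted for no gene and no list.

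The test, the filter, 30 gene lists, 7 lists of cell type markers and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those that passed with no overlap between the groups; 12 genes whether or not they passed; and up to 4 members of each list, the 3 with the smallest adjusted p among those that passed and the brightest one that did not. Other genes are said to have been chosen after their values were seen. Lists with at least 5 measured genes were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the lists of a family. Each was also tested with the correlation between genes estimated from the arrays, and with fry, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes.

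The procedure was tested on simulated data for this comparison, with 3 arrays per group and 22518 probe sets of which 200 were changed, in 10 data sets. With independent noise, 27.4% of changes of 1 log2, 72.8% of changes of 2 log2 and 86.0% of changes of 3 log2 were called, with a mean of 6.1 false calls per data set. This noise was drawn from the variance trend that limma had fitted to the real arrays, so the simulation could not test that variance model. In 20 simulated data sets of 11332 genes with 30 lists of 25 genes, camera called the list shifted by 0.4 log2 in 20 data sets, camera with an estimated correlation in 15 and fry in 14; camera and fry called 0 of the unshifted lists. These lists had no correlation between genes, which real lists have.

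The alternatives were quantile normalization, median centring and cyclic loess; an offset of 2.9, the 20th percentile of all signals; no filter and filters at the 25th and 75th percentile; eBayes without trend and robust eBayes; array weights; the replicate number as a block; a fold threshold of 1 log2; the mean of all probe sets of a gene; leaving out probe sets whose names end in x_at or s_at; and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.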

Results

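HL-1 cells, which keep features of adult atrial cardiomyocytes in culture, were profiled after 8 hours at 1% oxygen (hypoxia, 3 arrays) or 21% oxygen (normoxia, 3 arrays). The comparison asks how gene expression in these cells responds to low oxygen. Median signals of the 6 arrays lay between 15.0 and 19.0 and the brightest probe set of each array between 9203 and 11642. Signals of the atrial list varied widely between genes. Myl7, the atrial myosin regulatory light chain, had a signal of 8687 ± 852 in hypoxia and 8653 ± 636 in normoxia (SD, n = 3 arrays in each group, as throughout), and Myl4, the atrial essential light chain, 4763 ± 224 and 5175 ± 200. Kcna5 and Gja5, an atrial potassium channel and an atrial connexin, had signals of at most 6.13 in either group.

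Among the genes that passed the test, far more were higher than lower in hypoxia. The genes that rose included a glucose transporter and glycolytic enzymes, oxygen sensors, mitochondrial proteins and a natriuretic peptide. Of 11332 genes tested, 85 changed, 75 of them higher and 10 lower in hypoxia. Of these, 53 were higher and 5 lower by at least 1 log2. The median absolute log2 fold change was 1.26 among the genes that rose and 1.00 among those that fell. In all 85, the 3 arrays of one group lay on the same side of the 3 of the other; among all 22518 probe sets tested this held for 16.5%, where chance gives 10%. At probe set level 137 changed, 120 higher and 17 lower, and 2456 had an unadjusted p under 0.05. Of the genes that changed, 47 had another kept probe set. Another one passed in the same direction for 21 of them and had the opposite sign for 3, while 0 passed in the opposite direction. A further 8 genes, not counted here, passed only on a probe set that did not represent them. Without multiple-test adjustment, genes with p under 0.05 were split about evenly, 695 higher and 714 lower.

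**Figure D1:**
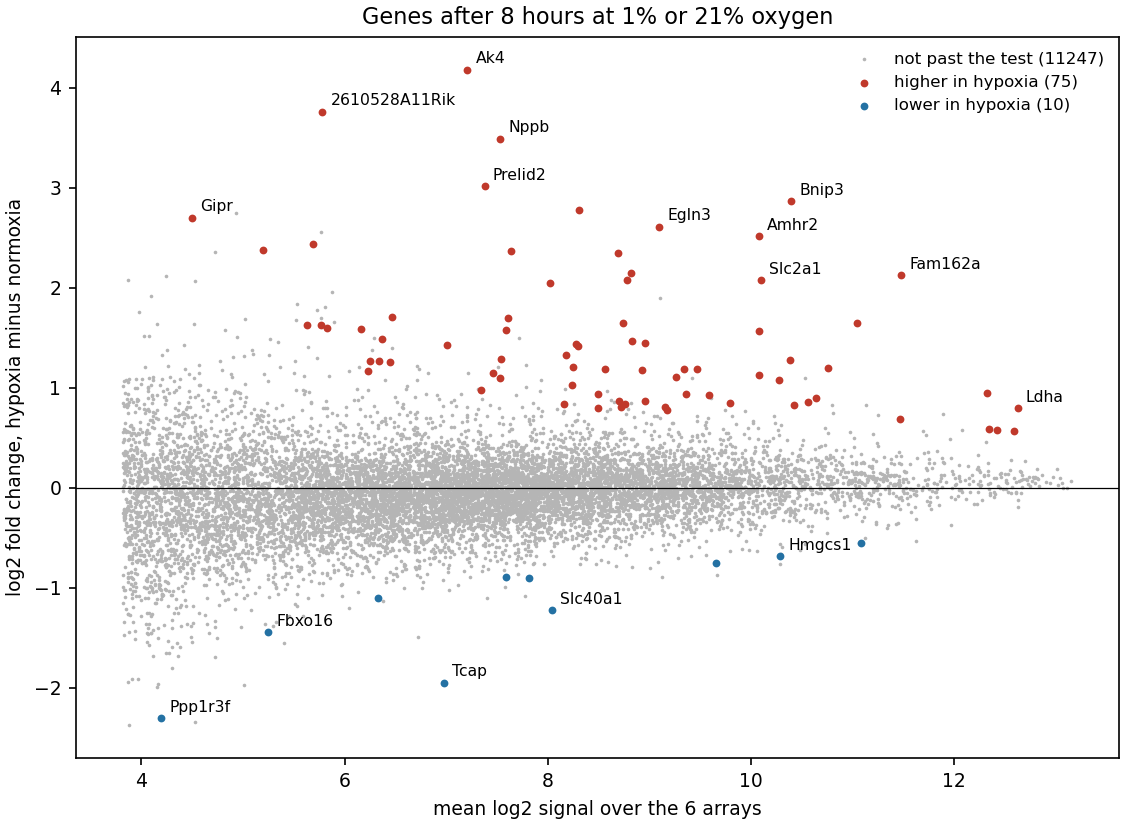
Log2 fold change of each of the 11332 genes (vertical axis, hypoxia minus normoxia) against its mean log2 signal over the 6 arrays (horizontal axis). Red points are the 75 genes that were higher, blue points the 10 that were lower and grey points the genes that did not pass; the largest rise is Ak4 at 4.18 and the largest fall Ppp1r3f at -2.30.

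Ak4, a mitochondrial adenylate kinase, showed the largest rise, 18.1-fold (log2 fold change 4.18, SE 0.32, adjusted p = 0.000659), from a signal of 38.4 ± 21.6 to 633 ± 45.5. The uncharacterized gene 2610528A11Rik rose by 3.76 on the log2 scale (SE 0.39), from 16.1 ± 7.64, close to the level of the filter, to 216 ± 95.9. Nppb, which encodes B-type natriuretic peptide, rose by 3.49 (SE 0.36), from 59.3 ± 29.5 to 655 ± 259. Prelid2 rose by 3.01 and Kbtbd11 by 2.78. Bnip3, a mitochondrial protein of mitophagy and cell death, rose 7.29-fold to one of the higher signals among the genes that rose (3674 ± 540 against 536 ± 246, adjusted p = 0.00138). Egln3, a prolyl hydroxylase that marks HIF proteins for degradation, rose by 2.61 (adjusted p = 0.0653 for the mean of its probe sets) and Ankrd37 by 2.44. Gipr, the receptor of the incretin GIP, rose by 2.70, but at signals of 62.2 ± 30.3 and 9.33 ± 3.55, the second of which is under the level of the filter. Amhr2, the receptor of anti-Müllerian hormone, rose 5.73-fold (SE 0.15 on the log2 scale, adjusted p = 0.00016), from 454 ± 60.3 to 2600 ± 378. Over all alternatives, the adjusted p of Bnip3, Kbtbd11 and 2610528A11Rik reached 0.055, that of Nppb and Prelid2 0.0604 and that of Egln3 0.0792. Of these 10 genes, all but Gipr passed in each fit with 1 array left out. Gipr did not pass without hypoxia replicate 1 (adjusted p = 0.215), hypoxia replicate 2 (0.127) or normoxia replicate 3 (0.106).

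The falls were fewer and smaller. Ppp1r3f, a phosphatase subunit, fell by 2.30 (SE 0.38), from 40.8 ± 6.28 to 8.40 ± 2.29, the second of which is under the level of the filter. Tcap, the titin cap protein of the Z-disc, fell by 1.95 (SE 0.19, adjusted p = 0.00154), from 249 ± 33.3 to 64.8 ± 10.9. Fbxo16 fell by 1.44 and Slc40a1, the cellular iron exporter ferroportin, by 1.22 (402 ± 36.3 against 173 ± 23.2, adjusted p = 0.00894). Ednrb, an endothelin receptor, fell by 1.10, with its other 2 probe sets at -0.41 and -0.49 (adjusted p = 0.633 and 0.561). The lipid droplet protein Fitm1 fell by 0.90, the orphan receptor Gpr22 by 0.89 and Mcrip2 by 0.76. Hmgcs1, the cytosolic synthase of HMG-CoA in the cholesterol pathway, fell by 0.68 on 1584 ± 67.8, and Tnni1, slow skeletal troponin I, by 0.55 on 2651 ± 211. Tcap was the only one of the 10 that passed in every fit with 1 array left out. Slc40a1 failed without normoxia replicate 3 alone (adjusted p = 0.077, range over all alternatives 0.000754 to 0.0899). The other 8 each failed without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 2 and normoxia replicate 3 (Fitm1 up to 0.153, Hmgcs1 0.142, Ppp1r3f 0.16, Fbxo16 0.175, Ednrb 0.176, Mcrip2 0.176, Gpr22 0.193 and Tnni1 0.279). Without hypoxia replicate 3, Fbxo16, Ednrb, Mcrip2 and Tnni1 failed too, and without normoxia replicate 1 Fbxo16 and Ppp1r3f. After centring each array on its median, only 4 genes were lower, and Ednrb, Fbxo16, Fitm1, Gpr22, Hmgcs1, Mcrip2 and Tnni1 did not pass.

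**Figure D2:**
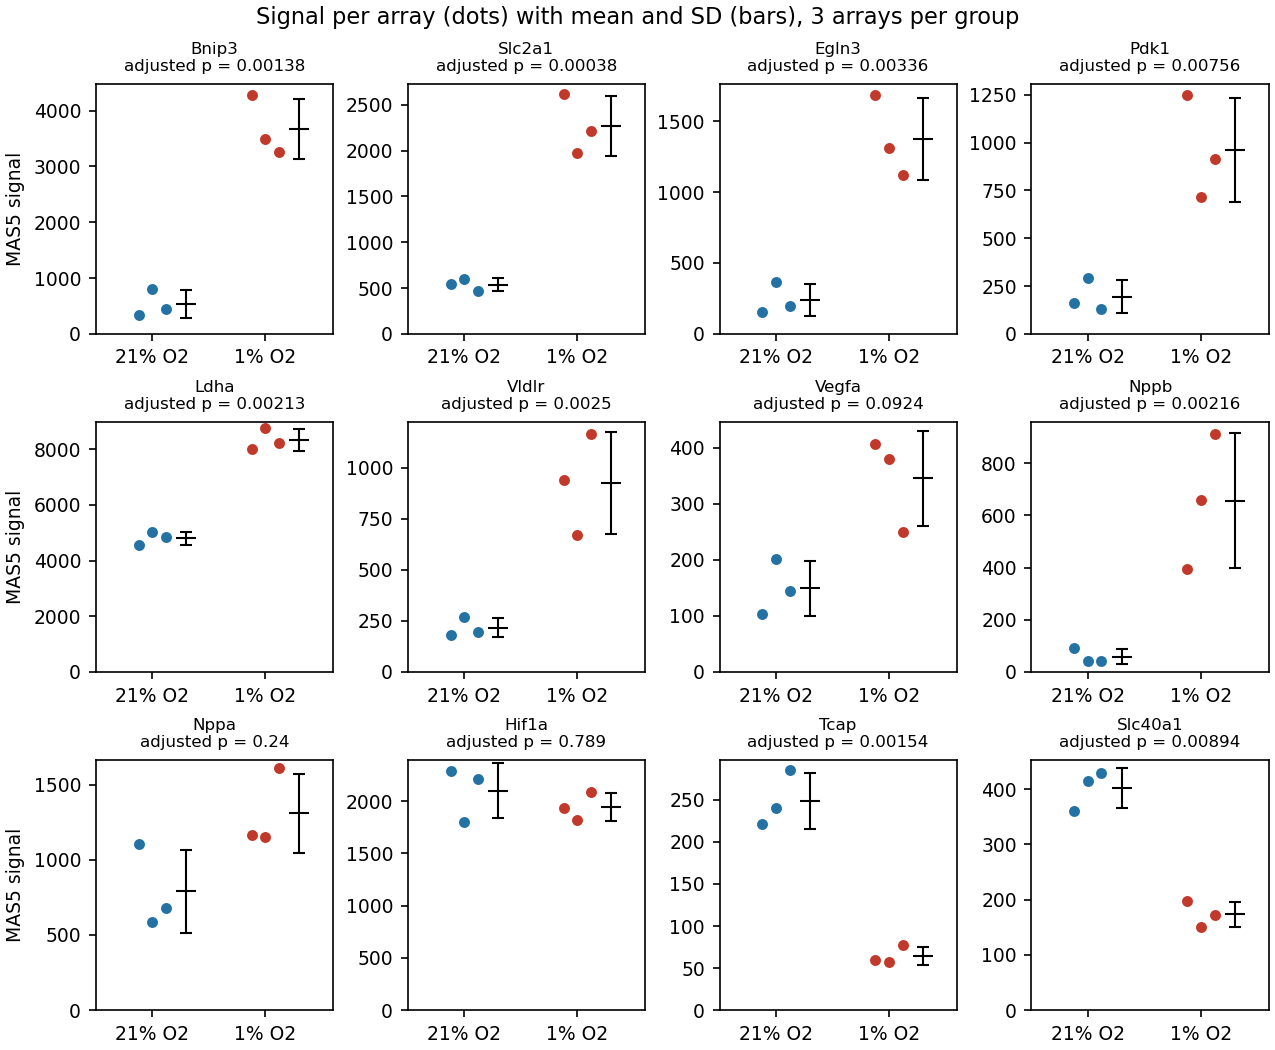
MAS5 signal on a linear axis for 12 genes, with each array as a dot (21% oxygen in blue, 1% oxygen in red) and the mean and SD of 3 arrays as black bars. The 2 groups do not overlap for Bnip3, Slc2a1, Egln3, Pdk1, Ldha, Vldlr, Vegfa, Nppb, Nppa, Tcap or Slc40a1, of which Vegfa (adjusted p = 0.0924) and Nppa (adjusted p = 0.24) did not pass the test over all probe sets, and they overlap for Hif1a.

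Glycolysis and glucose uptake formed the list with the smallest camera p. Of its 30 measured genes, 9 rose and 0 fell, while adjusted over the list alone 17 were higher and 2 lower. Pfkl, named after its values were seen, is not among the 9, as only a probe set that did not represent it passed. Its representative probe set had a log2 fold change of 1.90 (adjusted p = 0.0952). The median log2 fold change of the list was 0.53 (camera adjusted p = 1.21e-10). The call was lost with the correlation between genes estimated (adjusted p = 0.173 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose 4.22-fold (2272 ± 326 against 538 ± 66.6, adjusted p = 0.00038). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 2.35 (adjusted p = 0.00756; 0.0716 without hypoxia replicate 1, range over all alternatives 0.000529 to 0.102). Tpi1 and Ldha, very bright enzymes at the middle and end of the pathway, rose 1.93-fold and 1.74-fold, the latter from 4804 ± 240 to 8335 ± 391. The other genes that rose were Pfkp by 0.90, Pgm1 by 0.93, Hk2 by 0.78, Aldoa by 0.58 and Pgk1 by 0.57, named after their values were seen. Without hypoxia replicate 1 none of these 5 passed (Pfkp 0.0535, Pgm1 0.0822, Pgk1 0.0896, Aldoa 0.177 and Hk2 0.237). Pgk1, Aldoa and Hk2 failed also without hypoxia replicate 2, all but Pfkp without normoxia replicate 3, and Aldoa and Hk2 without normoxia replicate 1 or 2. Pgam1 had a log2 fold change of 0.49 and did not pass (adjusted p = 0.0589). It passed, among other alternatives, with the filter at the 75th percentile (adjusted p = 0.0362) and with array weights (0.0118), with a range over all alternatives of 0.00337 to 0.33. It also passed in the fit on the mean of all probe sets of a gene (0.0421). Its log2 fold change there stayed at 0.49, so no further probe set added support.

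The list of oxygen sensing and HIF feedback had 7 of 22 genes higher and 0 lower, or 12 and 0 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 8.48e-10, and adjusted p = 0.173 with an estimated correlation). Higd1a, a mitochondrial protein, rose by 1.65 (3786 ± 555 against 1210 ± 188). Beside Egln3 and Ankrd37, the others that rose, named after their values were seen, were Ndrg1 by 2.37, Rora by 1.63, Egln1, another HIF prolyl hydroxylase, by 1.56, and the transcription factor Bhlhe40 by 1.19. Without hypoxia replicate 1 these 4 did not pass (adjusted p = 0.0914, 0.109, 0.148 and 0.168). Ndrg1, Egln1 and Bhlhe40 failed also without hypoxia replicate 2, Rora, Egln1 and Bhlhe40 without normoxia replicate 3, and Bhlhe40 without normoxia replicate 2. The transcript of the oxygen-regulated transcription factor itself, Hif1a, had a log2 fold change of -0.10 (SE 0.12, adjusted p = 0.789; 1947 ± 134 against 2099 ± 266).

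Among angiogenic and vasoactive factors, 3 of 18 genes rose and 0 fell, or 5 and 1 adjusted over the list alone (median 0.21, camera adjusted p = 0.0103, and adjusted p = 0.173 with an estimated correlation). The list's call was also lost without hypoxia replicate 2 (adjusted p = 0.0589) and without normoxia replicate 1 (adjusted p = 0.089), with a range over the alternatives at the preset correlation of 0.00119 to 0.089. Stc1, a secreted glycoprotein, rose by 1.58, the peptide hormone Apln by 1.59 and the vasodilator peptide Adm by 0.69 on a high signal (3610 ± 114 against 2239 ± 163). Apln and Adm did not pass without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 3 (adjusted p up to 0.218 and 0.104). Vegfa, the main angiogenic growth factor of the list, had a fold change of 2.34 (345 ± 84.3 against 150 ± 48.9) that did not pass over all probe sets (adjusted p = 0.0924), and its other probe set had a log2 fold change of 1.17 (adjusted p = 0.207). It passed without hypoxia replicate 3 (adjusted p = 0.0403) and after median centring (adjusted p = 0.0304), with a range over all alternatives of 0.000352 to 0.367. Vegfb had a log2 fold change of -0.49 (SE 0.47, adjusted p = 0.739).

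Enzymes that modify collagen were among the genes that rose. In the list of collagen modification and matrix, 4 of 23 genes rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.37, camera adjusted p = 2.34e-05, and adjusted p = 0.173 with an estimated correlation). The prolyl hydroxylase subunits P4ha2 and P4ha1 rose by 2.04 and 1.03 and the lysyl hydroxylase Plod2 by 0.85 (adjusted p = 0.0202, or 0.0776 for the mean of its probe sets). The fourth was the matricellular protein Ccn1, by 1.33 (adjusted p = 0.0485), named after its values were seen. Sparc, a bright matrix protein, had a log2 fold change of 0.36 (adjusted p = 0.531). In the list of histone lysine demethylases, 2 of 19 genes rose and 0 fell, with the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.0103, and adjusted p = 0.173 with an estimated correlation). These were the demethylase Kdm3a by 1.19 and Jmjd6, better known as a lysyl hydroxylase, by 1.21, while Kdm1a had a log2 fold change of 0.01. Of the genes in these lists, P4ha2 passed in each fit with 1 array left out, whereas 5 others did not. Ccn1 passed only without normoxia replicate 1 (adjusted p = 0.02) and otherwise had adjusted p between 0.0638 without hypoxia replicate 1 and 0.221 without normoxia replicate 3. P4ha1, Plod2, Kdm3a and Jmjd6 each failed without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 3 (adjusted p up to 0.116, 0.146, 0.0911 and 0.176). Plod2 and Kdm3a failed also without normoxia replicate 2 and Jmjd6 also without normoxia replicate 1.

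Immediate early genes had a median log2 fold change of 0.53, with 2 of 19 higher and 0 lower, or 6 and 0 adjusted over the list alone (camera adjusted p = 4.73e-05, and adjusted p = 0.173 with an estimated correlation). Ier3 rose by 1.43 and the transcription factor Fos by 1.25, while Jund had a log2 fold change of 0.53 (adjusted p = 0.583). Among inhibitors of cyclin-dependent kinases and p53 targets, 2 of 19 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.32, camera adjusted p = 8.71e-06, and adjusted p = 0.173 with an estimated correlation). The cell cycle inhibitor Cdkn1a (p21) rose by 1.08 (1836 ± 387 against 864 ± 124) and Ccng2, an atypical cyclin, by 1.17. Ccng1, a p53 target, had a log2 fold change of 0.73 (adjusted p = 0.0911) and passed without normoxia replicate 1 (adjusted p = 0.00663, range over all alternatives 0.00199 to 0.378). Genes of the G2 and M phases were shifted slightly the same way, with 29 of 33 above 0 and a median of 0.15, but 0 passed over all probe sets or adjusted over the list alone (camera adjusted p = 8.71e-06, and adjusted p = 0.272 with an estimated correlation). Anln, the brightest of them, had a log2 fold change of 0.29 (adjusted p = 0.331). Of the named genes that rose here, Ier3 failed without normoxia replicate 3 alone (adjusted p = 0.0617). Fos, Cdkn1a and Ccng2 failed without hypoxia replicate 1 or normoxia replicate 3 (adjusted p up to 0.199, 0.189 and 0.107). Fos and Cdkn1a failed also without hypoxia replicate 2 and Fos and Ccng2 also without normoxia replicate 2.

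Cholesterol synthesis and fatty acid oxidation were shifted lower as groups. In cholesterol synthesis, 20 of 22 genes were below 0 with a median of -0.37, and Hmgcs1 fell. Adjusted over the list alone, 7 were lower and 1 higher (camera adjusted p = 2.39e-06, and adjusted p = 0.0974 with an estimated correlation). Fdps, which makes farnesyl diphosphate, had a log2 fold change of -0.39 (adjusted p = 0.302). In fatty acid oxidation, 23 of 25 genes were below 0 with a median of -0.25, and 0 passed over all probe sets. Adjusted over the list alone 1 was lower (camera adjusted p = 8.71e-06, and adjusted p = 0.0974 with an estimated correlation). Hadh, the brightest of these, had a log2 fold change of -0.21 (adjusted p = 0.661). The TCA cycle had 16 of 18 genes below 0 and a median of -0.20 (camera adjusted p = 0.000822), and ion channels and calcium handling had 23 of 26 below 0 and a median of -0.21 (camera adjusted p = 0.00125). Both had an adjusted p = 0.173 with an estimated correlation. Triglyceride and phospholipid synthesis had a median of -0.20 (camera adjusted p = 0.0387, and adjusted p = 0.643 with an estimated correlation) and mitochondrial translation a median of -0.16 (camera adjusted p = 0.0096, and adjusted p = 0.46 with an estimated correlation). In these 4 lists 0 genes passed over all probe sets. Adjusted over the list alone, 1 was lower in the TCA cycle and 1 in triglyceride and phospholipid synthesis, and 0 in the other 2. Mdh2 of the TCA cycle had a log2 fold change of -0.06, the calcium pump Atp2a2 of -0.09, Scd2 of -0.04 and Mrpl39 of 0.14. The call for triglyceride and phospholipid synthesis was lost after median centring (adjusted p = 0.0667), with array weights (0.0726) and with the first within-group component, the main direction of spread between arrays of the same group, as covariate (0.0951). It was also lost without hypoxia replicate 2 (adjusted p = 0.0746), hypoxia replicate 3 (0.224), normoxia replicate 2 (0.178) or normoxia replicate 3 (0.098). That for mitochondrial translation was lost after median centring (adjusted p = 0.0741), without hypoxia replicate 2 (adjusted p = 0.18) and without normoxia replicate 1 (adjusted p = 0.247). Over the alternatives at the preset correlation these p-values ranged from 0.00425 to 0.224 and from 0.00037 to 0.247.

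**Figure D3:**
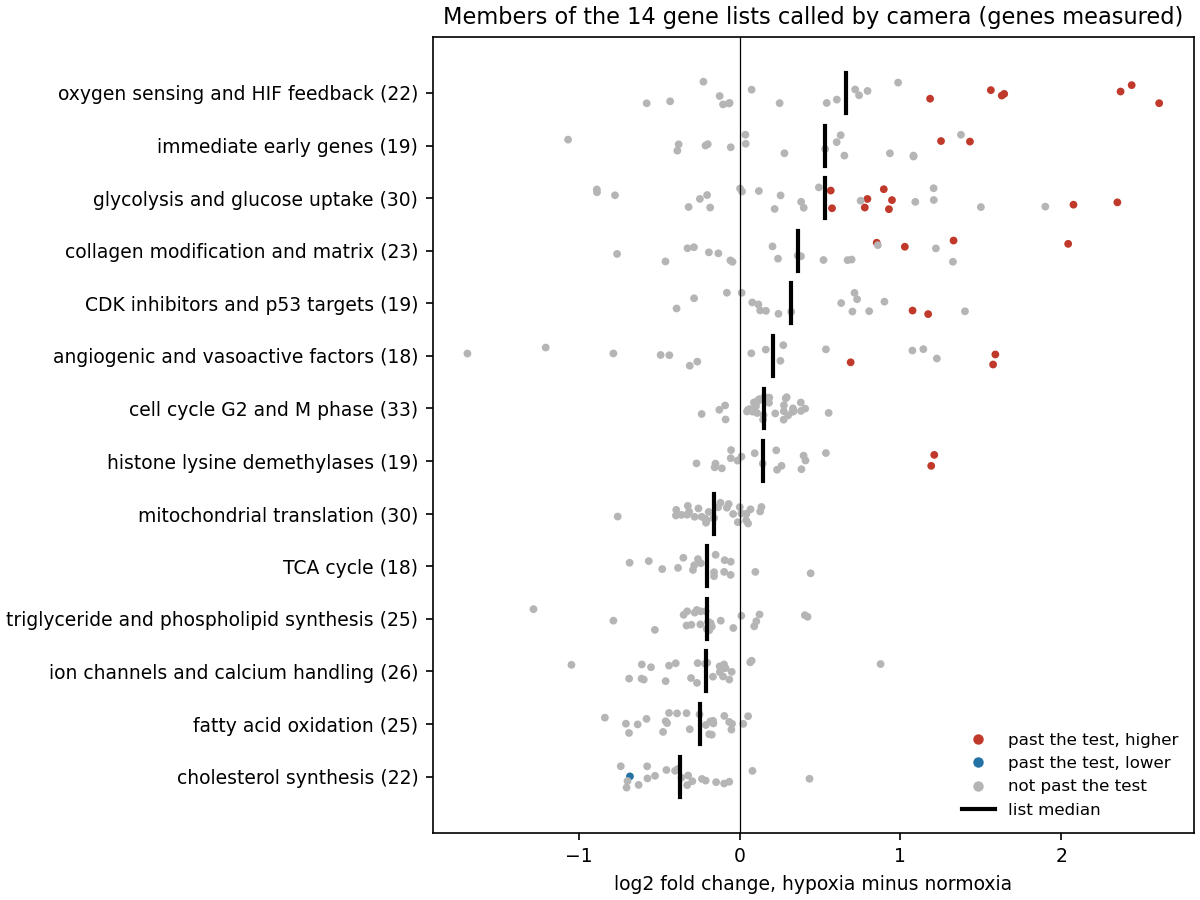
Log2 fold change (horizontal axis, hypoxia minus normoxia) of each measured gene of the 14 lists that camera called at its preset correlation, 8 higher and 6 lower, with the number of genes measured in brackets and the list median as a black bar. Genes past the test over all probe sets are red or blue; they reach 9 of 30 in glycolysis and glucose uptake, whereas in fatty acid oxidation 0 of 25 passed.

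In all, 14 of the 30 gene lists were called at the preset correlation of camera, 8 higher and 6 lower, and 0 with an estimated correlation. By fry, 8 moved on balance one way: glycolysis and glucose uptake, oxygen sensing and HIF feedback, angiogenic and vasoactive factors, and CDK inhibitors and p53 targets upward, and cholesterol synthesis, fatty acid oxidation, the TCA cycle, and ion channels and calcium handling downward. Changes in either direction were called by fry in 21 lists.

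Of the 16 lists without a call, several held single genes that changed. In the list of BNIP3, mitophagy and cell death, Bnip3 rose while 11 of 17 genes lay below 0, and adjusted over the list alone 2 were higher and 1 lower (median -0.12, mean 0.09, camera direction up, adjusted p = 0.96), and Cycs (cytochrome c) had a log2 fold change of -0.12. Bnip3l, a relative of Bnip3 in the list, was not counted because its probe sets are annotated to a pseudogene as well. All 3 of those above the filter rose, by 1.48, 1.58 and 1.64 (adjusted p = 0.00743, 0.00249 and 0.00132), named after their values were seen. In lipid uptake and lipid droplets, Vldlr, the VLDL receptor, rose 4.22-fold (927 ± 250 against 217 ± 47.2, adjusted p = 0.0025) and Fitm1 fell. The other 22 of 24 genes did not pass, with 3 higher and 2 lower adjusted over the list alone (median -0.05, or 0.06 after median centring, mean 0.01, camera direction up and fry down, camera adjusted p = 0.873). There, the lipid droplet genes Plin2 and Hilpda had log2 fold changes of 0.30 (adjusted p = 0.354) and 1.29 (adjusted p = 0.0924), the latter passing without normoxia replicate 1 (adjusted p = 0.0386, range over all alternatives 0.00546 to 0.367), and the fatty acid binding protein Fabp3 of -0.08. In the restraint of mTOR and autophagy, Ddit4, an mTOR inhibitor, rose by 1.29 and Map1lc3b had a log2 fold change of 0.01 (median 0.04, or -0.01 after cyclic loess, adjusted p = 0.386, with 1 gene higher adjusted over the list alone). This list was called without hypoxia replicate 3 (adjusted p = 0.034, range over the alternatives at the preset correlation 0.034 to 0.825, and adjusted p = 0.862 with an estimated correlation). Ddit4 failed without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 2 or normoxia replicate 3 (adjusted p up to 0.109).

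Among sarcomere genes Tcap and Tnni1 fell, and the other 25 of 27 did not pass (median 0.00, mean -0.11, adjusted p = 0.456); 1 was higher and 4 lower adjusted over the list alone. The median was negative after quantile normalization (-0.07), where the list was called lower (adjusted p = 0.0407), and cyclic loess (-0.12). As deposited it had an adjusted p = 0.862 with an estimated correlation. Myh6, the adult atrial and ventricular alpha myosin heavy chain, had a log2 fold change of 0.14 (SE 0.13). Among cardiac transcription factors and natriuretic peptides Nppb rose, and 2 were higher and 2 lower of 15 adjusted over the list alone (median -0.23, mean 0.07, camera direction down, adjusted p = 0.359). Nppa, the atrial natriuretic peptide, had a signal of 1308 ± 260 against 791 ± 276 (log2 fold change 0.76, adjusted p = 0.24; 0.0272 without normoxia replicate 1, range over all alternatives 0.00728 to 0.643), and Hopx a log2 fold change of -0.36 (adjusted p = 0.21). Among genes of iron, heme and metallothionein Slc40a1 fell and 5 of 16 were higher and 1 lower adjusted over the list alone (median -0.04, or 0.07 after median centring, mean 0.04, camera direction up, adjusted p = 0.533), with Fth1 at -0.16. Among inflammatory and interferon genes, the cytokine Mif rose by 0.58 (6413 ± 450 against 4274 ± 202), 3 were higher adjusted over the list alone (median 0.12, adjusted p = 0.17), and Vcam1 was at -0.09. Mif failed without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 2 or normoxia replicate 3 (adjusted p up to 0.104), after cyclic loess (adjusted p = 0.0857) and with no filter (adjusted p = 0.105), with a range over all alternatives of 0.00122 to 0.267. In pH regulation 0 of 10 genes passed and 2 were higher adjusted over the list alone (median 0.37, adjusted p = 0.101), among them Bsg at 0.74 (adjusted p = 0.0999; 0.00316 without hypoxia replicate 3, range over all alternatives 0.00069 to 0.373). The list itself was called without hypoxia replicate 3 (adjusted p = 0.00544), without normoxia replicate 2 (adjusted p = 0.0334) and without normoxia replicate 3 (adjusted p = 0.0402), with a range over the alternatives at the preset correlation of 0.00544 to 0.491. With all arrays it had an adjusted p = 0.46 with an estimated correlation.

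In the other 8 lists 0 genes passed in limma over all probe sets and, apart from 1 in ATF4 and amino acid stress, 0 adjusted over the list alone. Subunits of oxidative phosphorylation had a median of -0.02 over 50 genes (adjusted p = 0.539; 0.09 after median centring), and the list was called lower after quantile normalization (adjusted p = 3.91e-05) and cyclic loess (adjusted p = 2.92e-05). As deposited it had an adjusted p = 0.908 with an estimated correlation, with Cox4i1 at 0.06. The medians were 0.06 for the unfolded protein response (adjusted p = 0.234, Hspa5 at 0.18), -0.06 for ATF4 and amino acid stress (adjusted p = 0.859, mean 0.01, camera direction up, Eif4ebp1 at 0.05) and 0.06 for heat shock proteins (adjusted p = 0.783, mean 0.00, camera direction up and fry down, Hspa8 at 0.13). They were 0.01 for S phase (adjusted p = 0.533, Pcna at 0.16), -0.07 for ribosome biogenesis (adjusted p = 0.873, Npm1 at 0.25), -0.03 for redox defence (adjusted p = 0.942, Gpx3 at -0.07) and -0.04 for sphingolipid metabolism (adjusted p = 0.942, Cers5 at -0.06). The medians of ATF4 and amino acid stress, ribosome biogenesis, redox defence and sphingolipid metabolism were positive after median centring, and that of heat shock proteins was negative after quantile normalization and cyclic loess.

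Only 2 lists of cell type markers, smooth muscle and atrial, had enough measured genes for a test, and 0 were called with all arrays. The smooth muscle list had 6 measured genes, of which 3 (Notch3, Tagln and Cnn1) were higher adjusted over the list alone (median 0.22, camera adjusted p = 0.0859, and adjusted p = 0.581 with an estimated correlation). It was called without hypoxia replicate 1 (adjusted p = 0.0208), hypoxia replicate 3 (adjusted p = 0.0221) or normoxia replicate 3 (adjusted p = 0.0487), with a range over the alternatives at the preset correlation of 0.0208 to 0.554. Acta2, a smooth muscle actin, was bright in both groups (9450 ± 1242 against 8948 ± 731). The atrial list had 8 measured genes (median -0.17, camera adjusted p = 0.723, and adjusted p = 0.733 with an estimated correlation), with 2 (Sln and Nppa) higher adjusted over the list alone. Fibroblast, endothelial, leukocyte and skeletal muscle lists had 4 genes above the filter each and the ventricular list 3, too few for a test. In these, Dcn, Pecam1 and Ptprc had signals of at most 14.4 in either group, but other markers were above the filter. The endothelial genes Egfl7 and Vwf had signals of 198 ± 71.3 against 117 ± 17.2 and 98.7 ± 12.1 against 98.5 ± 14.1, and the leukocyte gene Cd68 44.0 ± 4.97 against 20.2 ± 4.56 (adjusted p = 0.157). The fibroblast gene Fbln1 had 644 ± 262 in hypoxia and 1215 ± 569 in normoxia. Marker genes other than Acta2, Myl7 and Nppa were named after their values were seen.

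The counts depend on single arrays and on the variance model. The number of genes that changed was 24 without hypoxia replicate 1, 37 without hypoxia replicate 2, 128 without normoxia replicate 1, 52 without normoxia replicate 2 and 27 without normoxia replicate 3. It was 9 for eBayes without a trend, 277 with array weights and 270 without hypoxia replicate 3 and normoxia replicate 1 together. Another split of the 6 arrays, which put hypoxia replicates 1 and 2 with normoxia replicate 2, called 17 gene lists with camera, more than the 14 of the real split.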

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

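The comparison with other splits, the component as covariate, raising low signals to the filter level and leaving out both hypoxia replicate 3 and normoxia replicate 1 were chosen after the main result was seen. All 85 genes that changed had the same sign in all 6 fits with 1 array left out. This adds little, as their groups did not overlap, and leaving out 1 array cannot then turn the sign of a probe set. Of the 85, 21 passed in each of these fits, and so did 17 of the 40 named genes that passed. No named gene that passed, and no gene list that was called, changed sign past the threshold in any alternative. The causes of the shifts below were not tested. eBayes without trend called 18 probe sets (16 higher, 2 lower) and 9 genes (7 higher, 2 lower). Of the 40 named genes that passed, 33 did not pass in that fit. Array weights called 437 probe sets (312 and 125) and 277 genes (197 and 80). The fit with the first within-group component as covariate called 696 probe sets (464 and 232) and 435 genes (290 and 145). Leaving out hypoxia replicate 3 and normoxia replicate 1, which had positive scores on it, called 439 probe sets (305 and 134) and 270 genes (182 and 88). Of the 85 genes, 82 were among them. The lowest score was that of normoxia replicate 2 (-36.0), with scores taken from the mean of all 6 arrays. Raising low signals to the filter level gave 29 probe sets and 19 genes lower. Median centring gave 113 genes higher and 4 lower and 8 probe sets lower; it moved the median log2 fold change of all probe sets from -0.04 to 0.07, an equal shift of every fold change, so falls are smaller relative to 0 but not relative to that median. A fold threshold of 1 log2, which can only lower a count, left 7 probe sets and 5 genes lower, and the mean of all probe sets of a gene gave 17 genes lower. With 1 array left out, probe sets that changed ranged from 39 to 200 (37 to 163 higher, 1 to 37 lower) and genes from 24 to 128 (22 to 101 higher, 1 to 27 lower). Of the genes that changed, 88.2% were higher; this was 85.0% after quantile normalization, 87.1% after cyclic loess and 96.6% after median centring. The other alternatives gave between 79 and 117 genes in all, apart from those with an array left out, the fold threshold (58) and the replicate block. With the replicate block, 105 probe sets changed (5 lower) and 63 genes (2 lower). Deviations of same-numbered arrays correlated at -0.08, 0.21 and -0.14. With 3 pairs and a large within-group component, this cannot settle whether the shared numbers pair the arrays, which were treated as unpaired. camera called 0 lists with an estimated correlation, fry called 8, and the list count was between 11 and 16 in the other alternatives. Of the 76 named genes, 9 were under the filter at the 75th percentile.

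There are only 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split called 137 probe sets and 85 genes and was the only 1 of the 10 with as many. The highest of the other 9 called 0 probe sets and 0 genes. Each of those 9 mixed hypoxia and normoxia arrays in both groups, so genes that respond to oxygen added to the spread within groups. A count of 0 was therefore likely there and does not measure chance. For gene lists, 2 of the 10 splits, the real one included, called at least the real 14, with 17 as the highest other. The split of hypoxia replicates 1 and 3 with normoxia replicate 1 had 2064 genes with an unadjusted p under 0.05, against 1409 in the real split, which points to a structure among the arrays. The planned ratio of 3' to 5' signal and its 2 alternatives were not run. Signals near or under the filter level of 14.1, as for Ppp1r3f and Gipr, limit fold changes there.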

Other observations

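Of the tests below, those on cyclic loess, same-numbered arrays and carried-over RNA, and the fits with the component as covariate or without 2 arrays, were chosen after the results they measure were seen. The genes in the next paragraph were also picked after their values were seen.

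Of the 85 genes that changed, 46 were in none of the fixed lists, 41 higher and 5 lower. Fam162a, a mitochondrial protein, rose 4.37-fold to a signal of 5995 ± 283. The copper transporter Atp7b rose by 2.38 and Selenbp1 by 2.15. Ero1a, an oxidase of the endoplasmic reticulum, rose by 1.64 and Kdelr3, which retrieves proteins to that compartment, by 1.70, while the list of the unfolded protein response was not called. Lgals3 (galectin-3) rose by 1.45 and the membrane-binding Anxa2 by 1.28, on 862 ± 83.3 in normoxia. The leukotriene enzyme Lta4h rose by 1.20 to 2640 ± 312, and the circadian repressor Ciart rose by 1.17. The glycogen-targeting subunit Ppp1r3c rose by 1.26 and its relative Ppp1r3f fell by 2.30, the latter near background. Of these rises, Fam162a and Anxa2 passed in all 6 fits with 1 array left out. Without hypoxia replicate 1, Lgals3 (adjusted p = 0.0629), Lta4h (0.0638), Kdelr3 (0.0889), Selenbp1 (0.104), Atp7b (0.134), Ppp1r3c (0.189) and Ciart (0.238) did not pass, and Ero1a did not without normoxia replicate 3 (0.0572). Kdelr3, Selenbp1, Atp7b and Ciart failed also without hypoxia replicate 2, these and Ppp1r3c without normoxia replicate 3, and Ciart and Ppp1r3c without any 1 of the other 3 arrays.

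Hypoxia replicate 3 and normoxia replicate 1 deviated from their groups to the same side of 1 common component. It was the largest of 4, with 42.3% of the variance within groups. Scores on it, taken from the mean of all 6 arrays, were 54.1 and 36.0 for these 2 arrays. They were -36.0 for normoxia replicate 2 and -25.8 to -6.2 for the other 3 arrays. The scores are not deviations from the groups, as they also hold a difference of 14.7 between hypoxia and normoxia. Across probe sets, the log2 fold changes correlated at 0.21 with the weights on the component (loadings). Some genes with extreme loadings were picked after the values were seen. Of these, Rgma, Slc16a3 and Fkbp8 were lower and Nppb, Ankrd1 and Synpo2l higher on hypoxia replicate 3 and normoxia replicate 1 than their groups would give. These directions follow from the choice by loading. Different scaling of the arrays is argued against by a share of 41.9% after cyclic loess. Unrelated hybridization of single probe sets is argued against by loadings that correlated at 0.31 across 5245 pairs of probe sets of the same gene. The correlation was 0.28 across 3235 pairs without a name suffix, and the highest of 1000 shuffled pairings gave 0.05. This is weak evidence, as such pairs can share probes. The lowest correlation of same-numbered deviations was -0.14. It cannot decide on a batch shared by replicate number, as the deviations are dominated by a component carried by 2 arrays with different numbers. Differences in RNA quality, labelling or the state of the cultures stay open and were not tested, and the design names no biological difference here. With the component as covariate, 435 genes changed in place of 85, all 85 among them. The component, however, was taken from the deviations of these same arrays. In simulated data with a component, its scores were shuffled over the 6 arrays and given random signs, so they could differ between the groups. There the covariate made little difference. With it, 32.0% of changes of 1 log2 and 78.8% of changes of 3 log2 were called, against 28.2% and 82.2% without it. False calls were 3.1 and 2.2. Because the simulated scores were set differently from the real ones, this cannot tell how many of the 435 genes truly changed.

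Normoxia replicate 2 had higher levels of the most induced genes than the other 2 normoxia arrays. Over the 18 genes that rose by at least 2 log2, the median excess was 0.67; it was 1.05 for Bnip3, 1.29 for Ak4 and 1.08 for Egln3, but 0.00 for Amhr2 and -0.54 for Nppb. If RNA had been carried over from a hypoxia sample at the median share of 9.21% of the hypoxia increase, the other 57 genes that rose should have a median excess of 0.15. Theirs was 0.02 (95% bootstrap interval over genes -0.02 to 0.11). That interval measures the spread between genes on 1 array. These 57 genes were also selected by the test, which favours genes whose normoxia arrays lie close together and so an excess near 0. The comparison therefore cannot decide on carried-over RNA. Removing the first within-group component left a median of 0.37 (quartiles 0.12 and 0.67), but this array helped to define the component, so a smaller excess follows by construction, and the component and other sources of the excess cannot be told apart. A mild lack of oxygen in that culture is a further candidate explanation, not tested here; if so, the fold changes of these genes might be understated.

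Amhr2 rose on all 3 of its probe sets, by 2.52, 2.16 and 2.31. The hypothesis that its signal reflects transcription from the neighbouring genes is argued against by the measured genes on either side, with log2 fold changes of -0.09 for Sp1 and 0.11 for Prr13. More widely, 100 measured neighbours of the genes that rose were examined, leaving out neighbours that had themselves been called higher. Their median log2 fold change was 0.01, at the 87.5th percentile of 10000 random gene sets matched on mean signal and drawn without the genes called higher. None of the 100 passed the limma test, but for rises this was fixed by the choice of neighbours. A shared induction strong enough to be called could therefore not be seen, and a weaker shift of the remaining neighbours was not seen. Cross-hybridization with another transcript stays open, as no probe sequences were used here.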
